A study of Mus musculus with 6 samples.

How the data were processed

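The series profiled trimethylation of lysine 27 of histone H3 (H3K27me3) by chromatin immunoprecipitation and sequencing (ChIP-seq) in spermatogenic cells of 6-week-old mice. The labels give 2 control libraries and 2 Ezh2 mutant libraries, plus 1 input sample per genotype, for which no processed file was used here. Cells were dissociated enzymatically and separated from somatic cells on Percoll and with strainers, per the labels' protocols, which put the share of spermatogenic cells at 90%. Libraries were sequenced on a HiSeq2000, per the labels' protocols. All 6 samples were assigned to groups from their titles, and the 4 ChIP libraries entered the comparisons. Nothing in the labels says whether replicates came from separate animals, so the spread between libraries may be partly technical.

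The authors deposited, for each ChIP library separately, a list of peaks and a list of enriched bins. The deposited peak lists come from MACS2, per the file headers, and hold only the chromosome, start and end of each peak, with no height, fold or p-value. The deposited bin lists come from hiddenDomains, a hidden Markov model caller, per the file names, and carry a display score that takes 4 values. That caller is meant for broad marks, and its bins are 200 bp wide except for 1 bin in control 1. The meaning of that score is not given in the sources used here, and between 91.0% and 93.1% of the bins of each library carry the highest score of 1000. Coordinates are in the mm9 build, and Bowtie, SAMtools and bedtools were used, per the submitters' processing notes. Versions, calling thresholds, the control track behind each list and the read depth are not given in the sources used here. Each MACS2 file name pairs the library with a label for its own genotype, so the lists of the 2 genotypes may rest on different control tracks. A deeper or cleaner library yields more and wider calls at a fixed threshold, so numbers of calls and covered lengths are not normalised for depth, and the depth behind each call is unknown.

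No mm9 annotation was used here. The gene table given is of GRCm38, whose coordinates differ, and no position was converted. Comparisons of genes and of 15 gene lists fixed beforehand were therefore not made, and regions are named by mm9 coordinate, counted from 1. Peaks and bins of a library that touch were joined, and coverage was computed in base pairs. The number of calls and the covered length per library were compared by two-sided exact permutation tests. With 2 libraries against 2 such a test cannot give a p below 0.333. Overlap between libraries was the Jaccard index, the base pairs shared by both libraries over the base pairs covered by either. Regions were the union of the 4 lists, merged where peaks share at least 1 bp or touch. A region was control-only when called in both controls and neither mutant, and mutant-only in the reverse case. The same counts were made for the 2 crossed splits, each setting 1 control and 1 mutant against the other control and mutant. They give the number produced by differences between libraries of the same genotype. Anything the libraries of a genotype share, such as a control track or a preparation, does not enter them. Retention by width was computed on regions merged from the 2 libraries of 1 genotype, so that the other genotype could not set the width. That definition was chosen after seeing the data, and so were a stricter rule, by which each library covers at least 50% of the region, and a count for regions displaced by 1 Mb along the chromosome.

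Domain coverage was tested in 100-kb windows with limma (empirical Bayes with a trend) on log2(kb covered + 1), over windows with a mean of at least 1 kb, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences on this scale understate changes in sparsely covered windows. This test and the interval calculations were tested on simulated data. All 5 checks on 400 planted intervals returned the planted values. With 9183 windows simulated from the real means, spread and library totals, the mutant against control fit without scaling recovered 81% of 100 windows changed by 1 log2 unit and 98% of 100 changed by 2, with 10 false calls. With totals scaled to be equal it recovered 68% and 92%, with 2 false calls. The changed windows were drawn only from the more densely covered ones, and the simulated noise was independent and normal. These rates therefore do not give the power of the test over all windows.

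The rule for naming regions was fixed before the data were examined, and so were the main tests. It takes the 5 widest control-only, mutant-only and shared regions and the 3 windows of lowest p in each direction. Alternatives fixed at the same time changed the caller, the score minimum, the overlap that counts, the merging distance, the chromosomes used, the window size, the pseudocount, the coverage minimum, the scaling, a block for replicate number, and each library left out in turn. Chromosome lengths were taken as the last called position in any list. Shares of peaks on a chromosome carry 95% Clopper-Pearson intervals, and a count of 0 a limit of 3 calls. Both cover counting error only. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.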

Results

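H3K27me3 is the repressive histone mark laid down by Polycomb repressive complex 2 (PRC2), whose catalytic subunit is either EZH2 or its paralog EZH1. The study asked what happens to the mark in male germ cells when Ezh2 is removed with a Cre recombinase driven by Mvh, a germ cell gene. H3K27me3 was mapped in spermatogenic cells of 6-week-old mice by ChIP-seq. Controls carried the Cre with a floxed and a wild-type Ezh2 allele (2 libraries), and mutants carried the Cre with only floxed alleles (2 libraries). The cells were a mixture of spermatogenic stages, and the labels put their purity at 90%. Each library was represented by its own MACS2 peak list and by its own list of bins called by hiddenDomains. Read depth was unknown. Nothing in the labels says that the libraries of a genotype came from separate animals. The p-values of exact permutation and limma tests between genotypes therefore measure only the spread between these libraries. Those of tests over regions or blocks of the genome do not measure that spread.

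The first comparison asked how much of the genome was called for H3K27me3 in the control and the Ezh2 mutant libraries. Calls give no level of the mark, so a region called in both genotypes may still differ in level. Loss of EZH2 was not measured here, and cells other than spermatogenic ones may add calls. MACS2 listed 32271 and 31863 peaks in the controls, and 42363 and 32094 in mutants 1 and 2. The means were 32067 ± 289 (SD, n = 2) in controls and 37229 ± 7261 (SD, n = 2) in mutants, and the difference was smaller than the spread between the mutants (exact permutation p = 0.667, two-sided). Without mutant 1 the mutant value exceeded the control mean by only 27 peaks. Peaks covered 67.3 and 69.8 Mb in the controls against 82.0 and 64.4 Mb in the mutants, a mean difference of 4.60 Mb that became -4.19 Mb without mutant 1 (exact permutation p = 1, two-sided). With hiddenDomains the covered length of both mutants lay below that of both controls. Enriched bins covered 53.4 and 54.3 Mb in the controls against 50.9 and 44.6 Mb in the mutants, a mean difference of -6.07 Mb or -11.3%. The exact p of 0.333 was the smallest that 2 libraries against 2 can give. Without mutant 1 that difference was -9.18 Mb and without mutant 2 it was -2.96 Mb. The number of merged hiddenDomains domains did not separate the genotypes, at 26011 and 25439 in the controls and 27365 and 22015 in mutants 1 and 2 (exact permutation p = 1, two-sided). The mean difference of -1035 domains became 1640 without mutant 2 and -3710 without mutant 1.

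**Figure D1:**
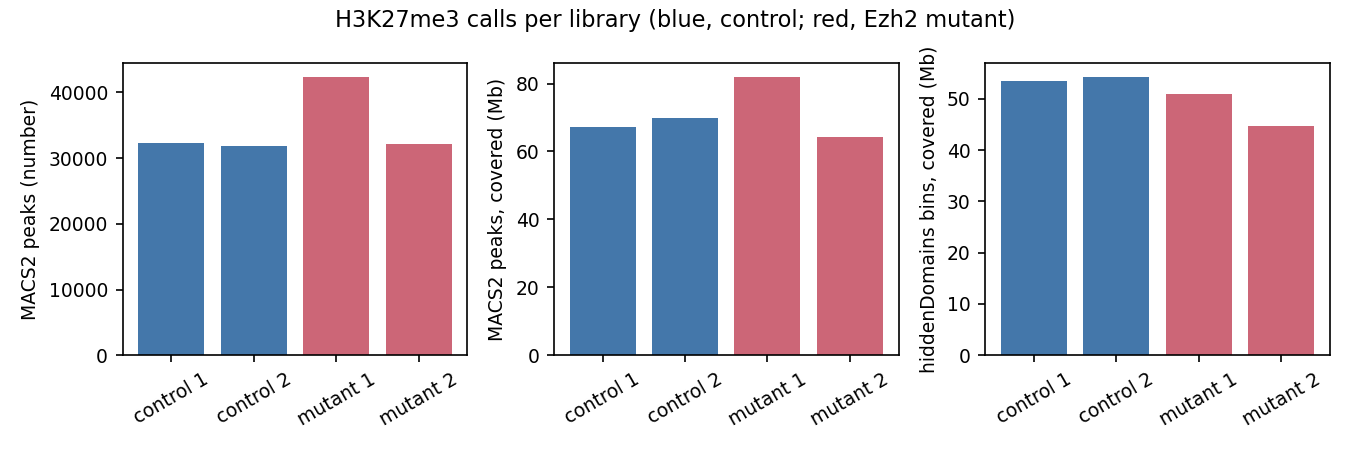
Number of MACS2 peaks, megabases covered by MACS2 peaks and megabases covered by hiddenDomains bins in each library, with 1 bar per library and no error bars. Mutant 1 stands above the other libraries at 42363 peaks, while hiddenDomains coverage of both mutants (50.9 and 44.6 Mb) lies below that of both controls (53.4 and 54.3 Mb).

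The next question was whether the width of the marked regions differed. The median MACS2 peak was 1477 and 1555 bp wide in the controls and 1243 and 1315 bp in the mutants, a mean difference of -237 bp. Peaks under 1 kb made up 33.8% ± 1.86 (SD, n = 2) of control peaks and 39.7% ± 1.49 (SD, n = 2) of mutant peaks. Peaks of 1 to 5 kb made up 59.1% ± 1.34 (SD, n = 2) and 53.8% ± 1.39 (SD, n = 2). Very broad peaks of over 20 kb numbered 63 and 77 in the controls and 96 and 75 in the mutants, and held 2.81% and 3.38% of the covered base pairs on average. The libraries of the 2 genotypes did not overlap in median width or in the share of peaks under 1 kb (exact permutation p = 0.333 for each, the smallest possible).

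A further comparison asked whether the same places were marked. Most H3K27me3 regions called in both controls were called in both mutants. Of 54748 merged MACS2 regions, 19923 were called in all 4 libraries. Of the 25339 regions called in both controls, 78.6% were called in both mutants, 10.8% in 1 mutant and 10.6% in neither. Of the 25648 regions called in both mutants, 77.7% were called in both controls and 12.7% in neither. In controls 1 and 2 and mutant 2, regions shared by all 4 libraries held between 86.2% and 86.8% of the peak-covered base pairs. In mutant 1 they held 74.2%, as 11569 of its regions were called in that library alone. Between the 2 controls the Jaccard index of the MACS2 peaks was 0.703, and between the 2 mutants it was 0.592. Control and mutant libraries shared between 0.545 and 0.606 of their combined base pairs. By this index the mutants overlapped each other no more than mutant 2 overlapped the controls. Unequal covered lengths limit the index, and the mutants differed most in length, at 82.0 and 64.4 Mb. With hiddenDomains the indices were 0.800 between controls, 0.731 between mutants, and 0.660 to 0.695 between genotypes. The mean index within genotypes exceeded that between genotypes by 0.0726 with MACS2, and by 0.0183 without control 1, 0.0167 without control 2 and 0.157 without mutant 2.

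Retention was then compared between regions of different width. A region counted as called where a peak covered at least 1 bp of it, which favours wide regions. Among MACS2 regions merged from the controls alone, all 83 that were wider than 20 kb were called in both mutants. Of the 2730 control regions of 5 to 20 kb, 99.8% were called in both mutants and 2 in neither. Retention was 83.1% among the 19433 control regions of 1 to 5 kb and 33.7% among the 3295 under 1 kb. In the opposite direction, all 110 mutant regions wider than 20 kb were called in both controls. So were 97.4% of the 3031 mutant regions of 5 to 20 kb, 77.9% of those of 1 to 5 kb and 57.8% of those under 1 kb. With hiddenDomains, 99.9% of the 1930 control regions of 5 to 20 kb and 28.9% of the 2160 under 1 kb were called in both mutants. Mutant regions were retained more often with that caller, at 67.5% under 1 kb and 92.3% at 1 to 5 kb, against 28.9% and 80.1% of control regions. Over all widths, both controls retained 90.2% of the 18038 mutant regions and both mutants 76.7% of the 20979 control regions. The retained regions numbered 16262 and 16096, so this gap mostly restates that hiddenDomains gave fewer regions in the mutants. When each library had to cover at least 50% of the region, a rule added after seeing the data, both MACS2 lists of the mutants retained 22.4% of control regions under 1 kb. They retained 63.0% of those of 1 to 5 kb, 95.02% of those of 5 to 20 kb and all of those over 20 kb. By that rule both controls, from which the regions were merged, held 79.5%, 87.3%, 98.9% and 100% of them. In the opposite direction both controls retained 52.0%, 65.9%, 82.3% and 99.1% of the mutant regions, in the same order of width, and both mutants themselves held 75.9%, 78.6%, 93.5% and 100%. Control regions displaced by 1 Mb were touched by peaks of both mutants in 4.77%, 8.33%, 16.8% and 38.6% of cases. The share with any overlap thus rose with width there too, though the density of peaks around the regions was not held fixed. Regions called by MACS2 in 1 library alone were narrow as well, with median widths of 513 and 539 bp in the controls and 651 and 540 bp in the mutants. The peak lists give no signal strength with which to set weak calls apart from absent ones.

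**Figure D2:**
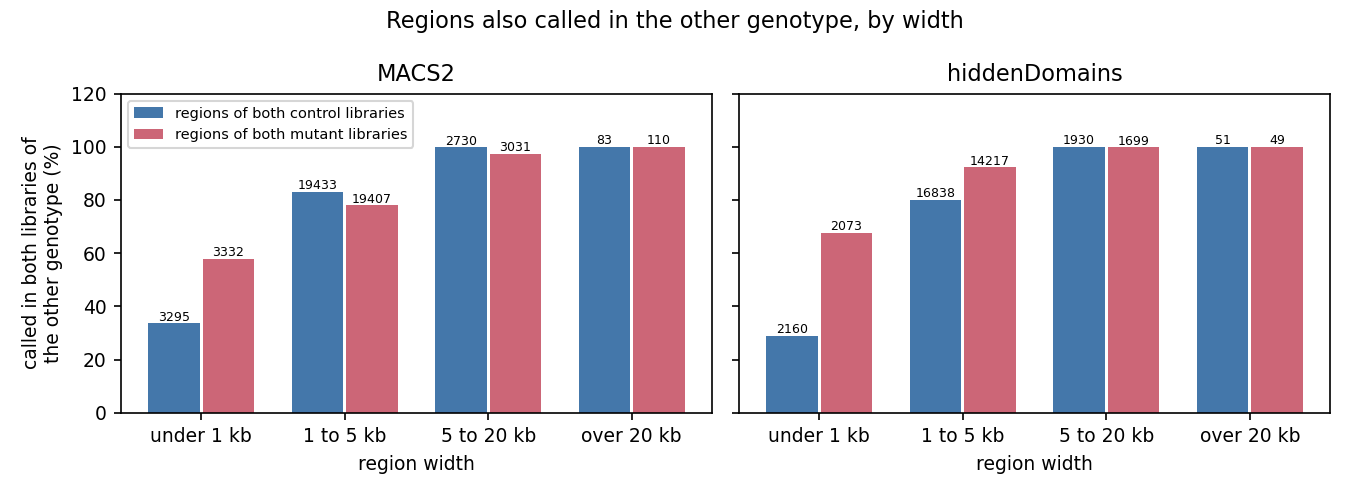
Percentage of the regions called in both libraries of 1 genotype that were also called in both libraries of the other genotype, by region width, for each caller. The number of regions stands above each bar. A region counts as called where at least 1 bp is covered. With MACS2, retention of control regions runs from 33.7% under 1 kb to 100% over 20 kb.

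The 4 widest regions called in all libraries were covered over similar lengths in both genotypes (mm9). The widest spanned chromosome 6 from 52099357 to 52228388, where MACS2 peaks covered 119 and 122 kb in the controls and 128 and 125 kb in the mutants. On chromosome 15 from 102736937 to 102853462 peaks covered 111 and 110 kb in the controls and 115 and 109 kb in the mutants. On chromosome 11 from 96108993 to 96219855 the covered lengths were 109 and 107 kb against 110 and 110 kb. On chromosome 2 from 74484372 to 74554982 they were 69.6 and 70.3 kb against 70.4 and 69.6 kb. The fifth, on chromosome 8 from 59788909 to 59835825, had 40.9 and 42.2 kb in the controls and 46.9 and 42.6 kb in the mutants. Bins called by hiddenDomains covered these regions to a similar extent in every library, for example 113 and 112 kb against 119 and 117 kb on chromosome 6.

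Control-only regions numbered 2685 and mutant-only regions 3269. The sum of 5954 was 4.12 times that of the higher of the crossed splits, which gave 1446 and 1380 regions. With hiddenDomains 2777 regions were control-only and 1034 mutant-only, a sum of 3811 against 686 and 573. The genotypes thus differed in more regions than the crossed splits under both callers, whereas the balance of the directions was not stable. A control track or preparation shared within a genotype could add to that excess, and an effect of Ezh2 cannot be told apart from it. With 1 mutant left out, the conditions are fewer and 7488 (without mutant 1) or 15102 (without mutant 2) regions were mutant-only. Control-only regions numbered 5718 without control 1, 5725 without control 2 and 4604 without mutant 1. Control-only regions made up 45.1% of the regions specific to a genotype with MACS2 and 72.9% with hiddenDomains. When the 31863 widest peaks were taken from each MACS2 list, an alternative chosen after seeing the data, they made up 59.9%. Only 910 control-only and 213 mutant-only MACS2 regions showed the same pattern in the bins of hiddenDomains. The remaining regions were for the most part called by MACS2 alone or by hiddenDomains in 1 library of the genotype.

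The regions specific to a genotype were short, with a median of 1044 bp for control-only and 1336 bp for mutant-only regions, against 2960 bp for regions called in all libraries. Mutant-only regions lay a median of 14.5 kb from the nearest shared region, about as far as shared regions lay from each other (15.9 kb). Control-only regions lay farther away, at 23.8 kb. The widest control-only region, on chromosome 6 from 16926556 to 16932622, had 3.80 and 3.34 kb of MACS2 peaks in the controls but no bin called by hiddenDomains. On chromosome 2 from 151396373 to 151401712, peaks covered 5.34 and 4.49 kb in the controls and bins 2.80 and 1.80 kb, with neither in the mutants. The other 3 of the widest 5 lay on chromosome 2 from 169578735 to 169583326, on chromosome 10 from 118544431 to 118548824 and on chromosome 15 from 98401722 to 98405793. Each of these held bins in both controls and in neither mutant. The widest mutant-only regions lay on chromosome 8 from 123676882 to 123685537 (8.66 and 1.94 kb of peaks), on chromosome 13 from 108033887 to 108040684 (6.45 and 3.70 kb) and on chromosome 18 from 35995010 to 36001333 (6.32 and 2.87 kb). The next lay on chromosome 5 from 120836188 to 120842285 (6.10 and 0.896 kb) and on chromosome 2 from 179949207 to 179955270 (5.43 and 1.98 kb). The regions on chromosomes 13 and 2 each also held 0.2 kb of hiddenDomains bins in 1 control. In all 5 the peaks were wider in mutant 1 than in mutant 2.

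**Figure D3:**
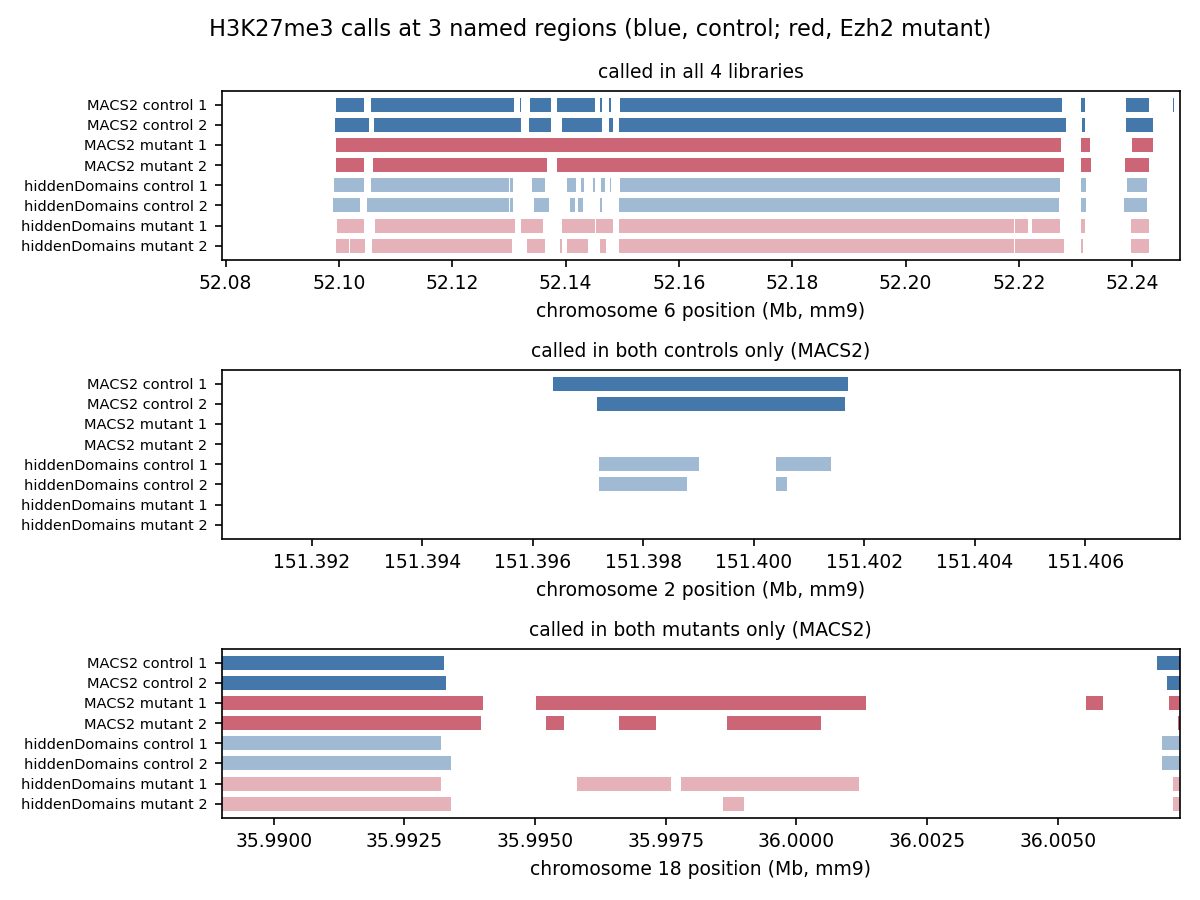
MACS2 peaks (dark) and hiddenDomains bins (pale) of each library along 3 regions in mm9 coordinates, with position in megabases on the horizontal axis and 1 row per caller and library. The chromosome 6 region is covered in all 4 libraries, the chromosome 2 region is called in the controls alone and the chromosome 18 region is called by MACS2 in the mutants alone, between stretches shared by all libraries. The chromosome 2 and 18 regions were picked from the named ones and are not the widest of their class. Both callers gave the same pattern in only 910 of 2685 control-only and 213 of 3269 mutant-only MACS2 regions.

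Regional gain and loss were then tested in 100-kb windows of domain coverage. No window of the 9183 tested passed the threshold with limma after Benjamini-Hochberg adjustment. The lowest adjusted p was 0.0559. At an unadjusted p under 0.05 there were 2766 windows, of which 2538 were lower and 228 higher in the mutants. With MACS2 peaks, where no window passed adjustment either, 1312 were lower and 964 higher at that level. The median log2 difference over all windows was -0.15 with hiddenDomains bins and -0.05 with MACS2 peaks. The hiddenDomains windows of lowest p included chromosome 8 from 32100001 to 32200000, with 5.2 and 5.2 kb covered in the controls and 1.4 and 1.4 kb in the mutants (log2 difference -1.37, SE 0.04, limma adjusted p = 0.0559). On chromosome 14 from 105000001 to 105100000 the covered lengths were 5.0 and 4.8 kb against 1.0 and 1.0 kb, and on chromosome 5 from 97700001 to 97800000 they were 4.0 and 3.8 kb against 0 and 0 kb. In the other direction, chromosome 7 from 143200001 to 143300000 had 4.2 and 4.2 kb in the controls and 9.4 and 8.8 kb in the mutants (log2 difference 0.96, SE 0.05, limma adjusted p = 0.0559). Chromosome 6 from 55300001 to 55400000 had 0 and 0 kb against 2.6 and 2.4 kb, and chromosome 17 from 15200001 to 15300000 had 0 and 0 kb against 2.2 and 2.2 kb. The same fit on the crossed splits gave 92 and 100 windows at an unadjusted limma p under 0.05, against 2766 between genotypes, and 0 after adjustment. In those splits a difference between genotypes adds to the spread within each pair, which lowers their counts. Anything the libraries of a genotype share, such as a control track, could add to the excess between genotypes.

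The outcome of this test depended on the settings. Without the minimum coverage 30 windows were higher and 622 lower in the mutants (limma, Benjamini-Hochberg adjusted p under 0.05), and 500-kb windows gave 4 and 403. It also depended on how the total coverage of the libraries was treated. With every library scaled to the same total, 173 windows rose and 340 fell in the mutants (limma, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05, 1285 windows were then lower and 819 higher, and the median log2 difference over all windows was -0.01. The windows that rose had a median of 4.1 kb covered in the controls and 7.5 kb in the mutants, and those that fell 4.3 and 1.55 kb before scaling. The chromosome 8 window then had a log2 difference of -1.24 (SE 0.12, limma adjusted p = 0.0238) and the chromosome 7 window one of 1.11 (SE 0.11, limma adjusted p = 0.0238). Windows that fell made up 66.3% of these calls. With the bins scaled, each crossed split gave 0 calls, and they gave 110 and 67 windows at an unadjusted limma p under 0.05. With MACS2 peaks scaled in the same way, added after seeing the data, 390 windows rose and 256 fell, so that 39.6% fell. At an unadjusted limma p under 0.05 the balance of these scaled peaks was the reverse, with 1484 windows lower and 1221 higher. Their median log2 difference was -0.12. The counts with scaled bins were 926 higher and 1497 lower without mutant 1, and 1023 and 1399 without mutant 2. They were 192 and 142 without control 1, and 147 and 127 without control 2.

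The last comparison set the X chromosome, which is transcriptionally silenced in meiosis, against the autosomes. The X was almost devoid of called H3K27me3 in both genotypes. No correction was made for the copy number or mappability of the X, so few calls need not mean a low level of the mark. MACS2 placed 78 and 89 peaks on the X in the controls, or 0.242% (95% Clopper-Pearson interval 0.191 to 0.302%) and 0.279% (0.224 to 0.344%) of all peaks. In the mutants it placed 134 and 86, or 0.316% (0.265 to 0.375%) and 0.268% (0.214 to 0.331%). Peak coverage was 0.810 and 0.998 kb per Mb of the X in the controls and 1.45 and 0.944 kb per Mb in the mutants. The autosomal density was 27.2 and 28.2 kb per Mb in the controls and 33.1 and 26.0 kb per Mb in the mutants. Autosomes were therefore covered between 22.9 and 33.6 times as densely as the X with MACS2. With hiddenDomains the ratio was 33.4 and 32.6 in the controls and 18.8 and 23.9 in the mutants. The difference between X and autosomes averaged -26.8 ± 0.59 (SD, n = 2) kb per Mb in controls and -28.3 ± 4.65 (SD, n = 2) in mutants, and did not separate the genotypes (exact permutation p = 1, two-sided). The mutant minus control difference of -1.55 kb per Mb became 1.74 without mutant 1 and -4.84 without mutant 2. With hiddenDomains it was 2.74 kb per Mb (exact permutation p = 0.333, the smallest possible). As the X carried so little, this measure followed the autosomes. With hiddenDomains the autosomal density differed by -2.48 kb per Mb and that of the X by 0.264, and with MACS2 they differed by 1.84 and 0.291.

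The share of the covered base pairs that lay on the X was higher in both mutants than in both controls. With hiddenDomains it was 0.201% and 0.206% in the controls and 0.357% and 0.281% in the mutants, with 107 and 112 kb covered in the controls and 182 and 126 kb in the mutants. With MACS2 it was 0.2003% and 0.238% against 0.294% and 0.244%, and the gap between control 2 and mutant 2 was within the spread of the controls. MACS2 peaks covered 135 and 166 kb of the X in the controls and 241 and 157 kb in the mutants. Mutant 2 thus covered less of the X than control 2, and its higher share came from lower autosomal coverage (64.2 against 69.7 Mb). The mean difference with MACS2 was 0.0498 percentage points, and 0.0250 without mutant 1 and 0.0311 without control 1. Each caller gave an exact p of 0.333, the smallest possible. No MACS2 peak lay on the Y chromosome in any library, which allows a share of up to between 0.0071% and 0.0094% of the peaks.

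Among autosomes, chromosome 11 was the most densely covered in every library under both callers, with 40.5, 42.3, 52.3 and 41.7 kb of MACS2 peaks per Mb in controls 1 and 2 and mutants 1 and 2. Several chromosomes shifted in their share of the coverage between genotypes by more than the controls differed. The share of chromosome 10 differed from the control mean by a log2 value of -0.32 in mutant 1 and -0.19 in mutant 2 with MACS2, and by -0.15 and -0.11 with hiddenDomains. Chromosomes 3 and 13 lay below the control mean in both mutants as well, at -0.18 and -0.10 and at -0.18 and -0.13 with MACS2. Chromosome 4 lay above it, at 0.22 and 0.14, and so did chromosome 11, at 0.08 and 0.10. The controls lay within 0.03 of their mean on every autosome. Control-only and mutant-only regions were spread accordingly. Chromosome 10 held 220 control-only and 98 mutant-only MACS2 regions, whereas chromosome 4 held 144 and 282 and chromosome 11 held 125 and 259. With hiddenDomains control-only regions were the more numerous on all 3, and only the shift relative to the genome was shared. They made up 88.0% of the regions specific to a genotype on chromosome 10, 59.3% on chromosome 4 and 64.3% on chromosome 11, against 72.9% over the genome. The spread over the 19 autosomes differed between control-only and mutant-only MACS2 regions (chi-square 238 on 18 degrees of freedom, p = 1.94e-40). This test is over regions, which are not independent replicates.

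**Figure D4:**
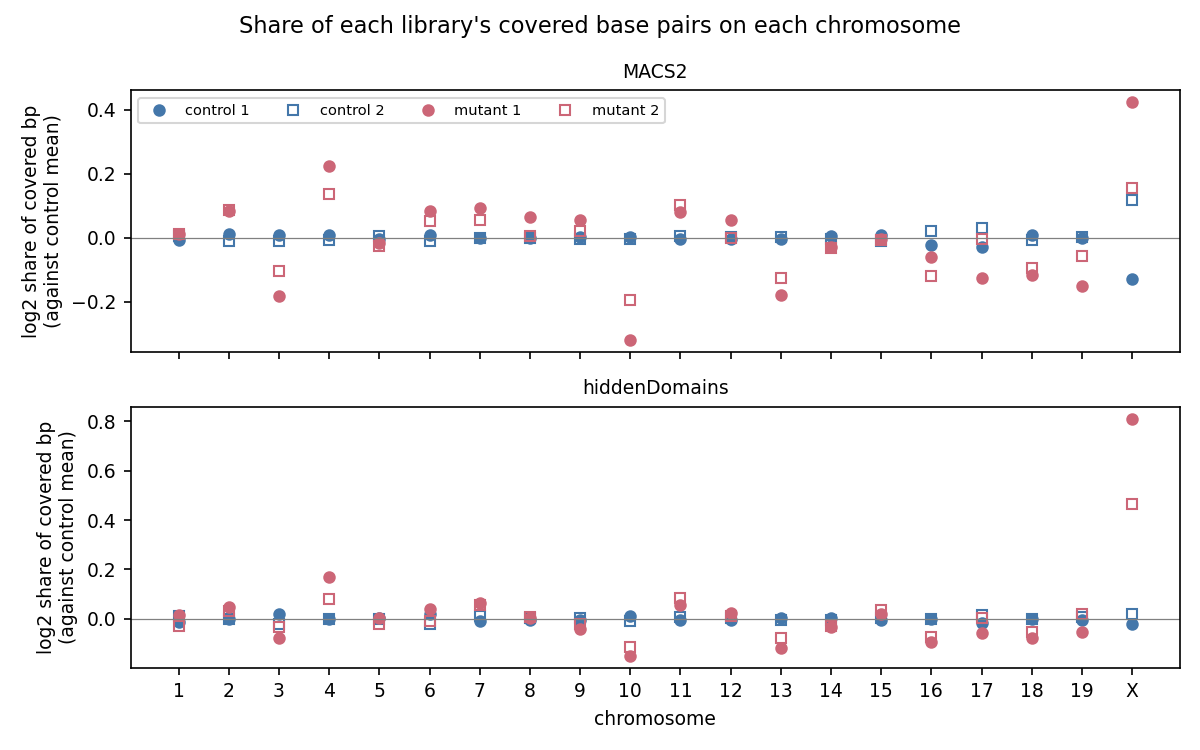
Log2 share of each library's covered base pairs on each chromosome, relative to the mean share of the 2 controls, for MACS2 peaks and hiddenDomains bins, with 1 point per library. Both mutants lie below the controls on chromosome 10 (-0.32 and -0.19 with MACS2) and above them on chromosome 4 (0.22 and 0.14) and on the X.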

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

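No comparison was made for the Y chromosome, as MACS2 called no peak there, although its bins were part of the hiddenDomains totals, overlaps and merged regions and of 1 of the 100-kb windows tested. The hiddenDomains lists held 14 bins on the Y in control 1, 15 in control 2, 9 in mutant 1 and 7 in mutant 2. Bins of 200 bp can adjoin and are not independent calls, so these counts were not tested against a limit. All of these bins lay at or below position 2899200 (mm9), and no control sample measured in the same way was used here.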

How the results depend on the processing

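Settings marked as added were chosen after the result was seen. Of 61 values under other settings 41 kept their sign and lay within 1.5 times the value with the main settings, as did 32 of 60 with 1 library left out. The cause of the other values was not tested unless stated. Counting only peaks of at least 1 kb (added) took the difference in peak number from 5162 to 1170 and that in MACS2 coverage from 4.60 to 2.40 Mb. With hiddenDomains in place of MACS2, mutant-only regions numbered 1034 and the mutant minus control difference between X and autosomes turned from -1.55 to 2.74 kb per Mb, while with the same number of widest peaks (added) it was -0.705. The X share difference was 0.116 percentage points with hiddenDomains and 0.0498 with MACS2. Requiring 50% of a region to be covered left 13212 regions in all 4 libraries. Applied to regions merged from 1 genotype (added), it took retention of control regions in both mutants from 33.7% to 22.4% under 1 kb, from 83.1% to 63.0% at 1 to 5 kb and from 99.8% to 95.02% at 5 to 20 kb. Retention of mutant regions in both controls went from 57.8% to 52.0%, from 77.9% to 65.9% and from 97.4% to 82.3%, as the rule is stricter by construction. Requiring the same pattern from both callers (added after seeing the data) left 910 control-only and 213 mutant-only regions. Dropping the coverage minimum gave 30 windows higher and 622 lower, 500-kb windows gave 4 and 403, and scaling to equal totals gave 173 and 340. Scaling MACS2 peaks (added) gave 390 and 256. The replicate block changed no call without scaling (0 windows higher and 0 lower) and with scaling gave 374 and 538 (added). Replicate numbers are known from the labels only. Deviations of same-numbered libraries correlated at r = 0.04, which cannot show whether those libraries were processed together. Leaving out 1 library at a time moved the difference in peak number between 27 (without mutant 1) and 10296, and in MACS2 coverage between -4.19 Mb (without mutant 1, reversed) and 13.4 Mb. It moved merged hiddenDomains domains between -3710 and 1640 (without mutant 2, reversed; all libraries, -1035), and hiddenDomains coverage between -9.18 and -2.96 Mb. The X minus autosome difference ranged from -4.84 to 1.74 kb per Mb (without mutant 1, reversed), and within minus between genotype overlap from 0.0167 to 0.157, against 0.0726 for all libraries. The X share difference ranged from 0.0250 to 0.0746 percentage points and that of peaks under 1 kb from 4.58 to 7.21. Fewer libraries make fewer conditions, so control-only regions numbered 3560 to 5725 and mutant-only regions 4490 to 15102 (without mutant 2). Shared regions numbered 20842 to 21822, and no window passed without scaling (0 to 0). With scaling, leaving out 1 library (added) gave 192 and 142 windows (control 1), 147 and 127 (control 2), 926 and 1497 (mutant 1), and 1023 and 1399 (mutant 2). There the lone library is assumed to vary like the other genotype. Score minimums and top-scoring subsets of MACS2 peaks were not run, as those lists hold no score; gene-based alternatives were not run, as no mm9 annotation was used. Depth is unknown, so a missing call is not evidence of a missing mark. Nor is a retained call evidence of an unchanged level.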

Other observations

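The tests on mutant 1 and on the distal X were written before their results were seen, and the other tests of this part were chosen after. The blocks named here were chosen after their values were seen. Beyond the chromosomes, coverage differed along them. On chromosome 5 from 35000001 to 40000000, MACS2 peaks covered 200 and 201 kb in the controls and 487 and 306 kb in mutants 1 and 2. On chromosome 2 from 175000001 to 180000000 they covered 132 and 105 kb against 272 and 161 kb, and on chromosome 7 from 140000001 to 145000000 they covered 160 and 168 kb against 375 and 214 kb. At the other end, chromosome 8 from 40000001 to 45000000 had 56.5 and 63.5 kb in the controls and 31.1 and 36.5 kb in the mutants. Each of these 4 blocks differed in the same direction with hiddenDomains, by log2 values of 0.54, 0.52, 0.49 and -0.21.

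The uneven spread of control-only and mutant-only regions over the autosomes may have a technical source. A difference in the copy number of whole chromosomes would shift all blocks of a chromosome together. Only 12.5% of the variance of the mutant minus control difference over 471 blocks of 5 Mb lay between chromosomes. Whole-chromosome differences therefore do not account for most of that variance. A difference in a few chromosomes would add little to it and is not excluded. A regional gradient in the libraries that is stronger in mutant 1 than in mutant 2 remained possible. Across blocks, mutant 1 minus mutant 2 correlated with mutant 2 minus the control mean at r = 0.467 (permutation p = 1e-05, the smallest possible; Spearman rho 0.420, p = 1e-05) with MACS2 and less strongly, at r = 0.223 (permutation p = 1e-05; Spearman rho 0.176, p = 0.00022), over 454 blocks with hiddenDomains, although mutant 2 enters these with opposite signs, which pulls the correlation below 0, and neighbouring blocks are not independent. GC content, different control tracks for the 2 genotypes, the mixed strain background and a graded loss of EZH2 could each give such a gradient, and none was tested.

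The excess of MACS2 peaks in mutant 1 may consist in part of weak calls. Of the 11569 regions called in mutant 1 alone, 13.3% held a hiddenDomains bin of that library, against 89.9% of the regions called in all 4 libraries. The former were also narrower, with a median of 651 bp against 2960 bp. The percentage was of the same order in the regions called only in control 1 (14.2%), control 2 (11.9%) or mutant 2 (7.75%). In number, 1534 such regions held a bin in mutant 1, 412 and 347 in controls 1 and 2 and 269 in mutant 2. The excess was not confined to MACS2. With hiddenDomains 6069 regions were called in mutant 1 alone, against 2684 and 2508 in controls 1 and 2 and 1825 in mutant 2. Depth and the control track, either of which could raise the number of weak calls, were not available to separate. No biological explanation was tested.

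The larger share of coverage on the X in the mutants was set against more permissive calling over the whole genome. Such calling predicts higher autosomal coverage in both mutants. With hiddenDomains the highest mutant value was 0.951 times the lowest control value, so that prediction was not met for that caller. Lower autosomal coverage itself raises the X share, however, and it was 44.5 Mb in mutant 2 against 53.3 and 54.1 Mb in the controls. Other differences in calling between the libraries therefore stay open. With MACS2, mutant 1 covered more of the autosomes (81.7 Mb) than either control. Calls near the distal end of the X are not the source. Without the last 1 Mb the lowest mutant share was still 1.35 times the highest control share with hiddenDomains, though 1.02 times with MACS2. A change in the mark on the X, a different mix of spermatogenic stages and a different share of somatic cells remain open and untested, as does the regional gradient.

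A hypothesis about the 4 widest shared regions is that they are the Hox gene clusters, classical Polycomb targets. In the GRCm38 gene table the 39 protein-coding Hox genes lie on chromosomes 6 (Hoxa), 11 (Hoxb), 15 (Hoxc) and 2 (Hoxd), and the 4 regions lie one each on these chromosomes. The idea came from seeing these chromosomes, so the 0.026% of 100000 random draws of 4 shared regions that fell on them restates the observation and does not test it. The 4 widest shared hiddenDomains regions were also on these chromosomes, and with MACS2 the fourth widest spanned 70.6 kb against 46.9 kb for the fifth. Chromosomes alone do not identify a locus, and without an mm9 annotation the hypothesis stays open.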
